A study of Gallus gallus with 66 samples.

How the data were processed

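Gene expression was measured on Affymetrix chicken arrays in preadipocytes of a lean and a fat chicken line, 66 arrays in 22 groups of 3. Per the labels, abdominal fat of 15 males aged 10 days was pooled for each line and digested, floating adipocytes were spun off and red cells were lysed. The groups of each line were the uncultured cells, passaged cultures at 50% confluence (named −12 h) and at 95% confluence (0 h), and cultures collected 12, 24, 72 and 120 h later, with 160 µg/ml oleate or without it (control). The labels call the 3 arrays of a group biological replicates, without saying whether they came from separate pools, dishes or days. All p-values therefore measure only the spread between these arrays, not between birds of a line. Biotin-labelled cRNA was prepared from 6 µg of total RNA, per the labels' protocols.

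The deposited table, used whole, gave a value for each of 38535 probe sets on each array. MAS5 is named, with no version or role, in the submitters' processing notes; no log or quantile step is recorded there. The unit of the deposited values was taken as log2 from the values themselves, which ran from −5.232 to 13.51 with a median of 4.17 on every array. The sorted values of any array differed from those of another by at most 0.0615, as quantile normalization leaves them, so the arrays have nearly the same distribution by construction. Differences below are log2 differences on that scale, and an error in the assumed log base would scale all of them alike. The number of arrays limits the precision; no read depth applies.

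Values were floored at 1.613, the median over arrays of the 20th percentile. Where values lie at the floor, the size of a difference depends on it: of 295 named results 52 had an array at the floor, and 48 of these were larger and 3 smaller in size without it. The 96 control probe sets of the array were set apart, fitted by themselves and adjusted over the 96. The 22060 probe sets above the array median (50th percentile) on all 3 arrays of at least 1 group were tested. Probe sets were matched to gene symbols through the platform annotation: 27178 named 1 gene, 177 named several and 11180 named none. The tested probe sets represented 10176 of the 13009 genes named. No genome was used and no coordinates are given. For a gene with several tested probe sets, the one with the highest mean over all arrays stood for the gene.

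A linear model with 22 group means was fitted to each probe set with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8, statmod 1.5.0), with moderated variances (trended prior, robust, 44 residual degrees of freedom, median prior degrees of freedom 5.79). Tests were two-sided and adjusted by Benjamini-Hochberg over the 22060 probe sets of a comparison; a probe set was called at an adjusted p under 0.05. The 18 comparisons were the oleate effect (oleate minus control, mean over both lines and 4 hours), that effect in each line and at each hour of each line, its difference between lines (fat minus lean), its change with time (120 h minus 12 h), the line difference (fat minus lean) in control cultures and in uncultured cells, the culture effect (0 h minus uncultured), the confluence effect (0 h minus −12 h) and time in control culture (120 h minus 12 h). Replicate numbers were not used as a block. Errors beside differences are standard errors (SE) of the fit.

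Lists of genes were fixed by hand: adipocyte identity; preadipocyte and stromal; fatty acid oxidation and PPAR targets; lipid droplet and triglyceride synthesis; fatty acid synthesis; cholesterol synthesis; cell cycle; extracellular matrix; contractile and smooth muscle; skeletal muscle; endothelial; macrophage and myeloid; lymphocyte; erythroid; mesothelial and epithelial; immediate early and dissociation; inflammatory and NF-kB; interferon response; unfolded protein and integrated stress; oxidative stress response; glycolysis and hypoxia; oxidative phosphorylation; cytosolic ribosomal proteins; bone and cartilage. Each of these 24 lists was tested in each comparison with camera (limma), which compares its members with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists. Members were counted as higher or lower after adjustment over all 22060 probe sets and, separately, adjusted over the list alone.

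The comparisons, the lists, the first set of alternative settings and the rule for named genes were fixed before the data were examined. That rule took, on the representative probe set, the 8 largest rises and 8 largest falls of the oleate effect, the line difference in control cultures and the culture effect. It took 5 and 5 for time in control culture, the line difference in uncultured cells, the confluence effect and the 2 tests of a difference between oleate effects. Each gene had to be called with the same sign in every line-by-hour part, and symbols of unnamed loci were passed over. To these were added up to 4 members of each list described, those with the smallest adjusted p, and members needed to state a count. The result of 1 gene that this rule named is not reported here.

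Every comparison was repeated under alternatives: no filter, a filter at the 70th percentile, no floor, an offset, quantile normalization, median centring, a replicate block, array weights, plain variances, 1 probe set per gene, only the arrays of the comparison, other choices of time points or line, and each array left out in turn. Further alternatives were chosen after seeing the data: centring on bright probe sets, a fit leaving aside uncultured arrays, culture series as a random block, macrophage markers as a covariate, removal of a shift tied to the style of array names, and each culture series left out for the interferon response, macrophage and inflammatory lists. A culture series is the arrays of 1 line and replicate number in 1 arm. For the block, arrays at −12 h and 0 h were counted with the oleate arm and uncultured arrays apart, giving 18 series of up to 6 arrays. A series left out for a list, or moved whole in a split, was its arrays from 12 to 120 h. Other splits of the same arrays, and splits that keep culture series whole or take out the main effect of time or line, were fitted to see how many probe sets a regrouping calls. The limma fit and the list test were first run on simulated data, with noise drawn for each array by itself. Real arrays of a culture series share part of their residuals (mean correlation 0.189 over 126 pairs). The shares and counts that follow therefore hold for independent arrays only. For the oleate effect, 79.1% of simulated 1.5-fold changes, 94% of 2-fold and 100% of 4-fold changes were called, with 6 of 21860 unchanged probe sets called. For a 3 against 3 comparison (fat line at 12 h) the shares were 20.9%, 49.3% and 87.9%. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.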

Results

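Expression of 10176 named genes was followed in preadipocytes of a lean and a fat chicken line, from freshly isolated cells through passage and confluence into 120 h of culture with or without oleate, the salt of a monounsaturated fatty acid. Each of the 22 groups held 3 arrays. Across tested probe sets, pairs of arrays of the same group correlated with a median r of 0.965 (66 pairs, 0.939 to 0.974), against 0.948 for pairs from different groups (2079 pairs). These are correlations over probe sets, which are not independent replicates. The labels write array names in 2 styles, with parts joined by a low bar or by dots. Control arrays from 12 to 120 h and fat-line arrays at −12 h have low-bar names, and the other arrays have dotted names, except that 1 (fat oleate 120 h replicate 3) has no name in the labels and was counted with its group. Every contrast of oleate with control is therefore also a contrast of styles. It is also a contrast of culture series, as shown by residuals of arrays with the same line and replicate number. Arrays at −12 h went with oleate arrays (mean correlation 0.15, 24 pairs, all above 0), in the fat line as well (0.144, 12 pairs), where their name styles differ. With control arrays they did not (0.014, 24 pairs), and control arrays went together between hours (0.179, 36 pairs).

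Oleate cultures (n = 24 arrays) carried more transcript of PLIN2, the coat protein of lipid droplets, than control cultures (n = 24). Its mean was 11.27 against 9.41, a log2 difference of 1.86 ± 0.10 (SE; adjusted p = 5.04e-20). By hour the PLIN2 difference was 2.28, 1.78, 1.42 and 1.74 in the lean line and 1.93, 1.93, 1.85 and 1.94 in the fat line at 12, 24, 72 and 120 h. Other large rises with the same sign in all 8 line-by-hour parts were MARF1 (2.03 ± 0.23), NUDCD1 (1.97 ± 0.12), CPNE3 (1.95 ± 0.14) and CEP350 (1.85 ± 0.14). NUDCD1, CPNE3 and CEP350 were also called higher in the contrast used for the shift between name styles (3.98, 2.69 and 2.08; adjusted p = 3.77e-07, 0.00285 and 0.0227). Less that shift MARF1 was at −0.15, NUDCD1 at −2.02, CPNE3 at −0.75 and CEP350 at −0.23. CSF3 (1.94 ± 0.42), S100A12 (1.90 ± 0.38) and IL4I1 (1.88 ± 0.33) rose as well, with adjusted p from 7.75e-19 to 0.00026 for these 7 genes. The largest falls were C1QTNF3 (−3.10 ± 0.39), SPTBN5 (−2.02 ± 0.20), LRRC17 (−1.70 ± 0.25) and PTN (−1.58 ± 0.24). TNFRSF11B (−1.5 ± 0.15), CDH8 (−1.48 ± 0.35), GAS2 (−1.42 ± 0.13) and BGN (−1.40 ± 0.21) followed. Adjusted p of these 8 falls ran from 8.73e-13 to 0.000712.

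Genes that handle fatty acids were among those that rose in oleate. In the fatty acid oxidation and PPAR target list 8 of 21 tested genes rose and 1 fell, with the same counts adjusted over the list alone (median 0.11, camera adjusted p = 0.00654). For these oxidation genes, adjusted p = 0.0836 with an estimated correlation. ANGPTL4, a lipoprotein lipase inhibitor, rose by 1.52 ± 0.14, and PDK4, which blocks pyruvate oxidation, by 1.42 ± 0.12. The acyl-CoA synthetase ACSL1 rose by 0.92 ± 0.08 and HADHB, of mitochondrial β-oxidation, by 0.36 ± 0.04. Adjusted p of the 4 ran from 1.82e-14 to 8.79e-10. Of 20 cholesterol synthesis genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.14, adjusted p = 0.0248). For cholesterol genes, adjusted p = 0.614 with an estimated correlation. Among them were the regulator SREBF2 (0.40 ± 0.06) and the mevalonate enzymes MVD (0.81 ± 0.13) and MVK (0.38 ± 0.08).

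Lists of the fat cell itself were not called in the oleate effect. In the adipocyte identity list 7 of 16 genes were higher and 2 lower (7 and 3 adjusted over the list alone; adjusted p = 0.132). The fatty acid carriers FABP4 (1.58 ± 0.26), CD36 (1.54 ± 0.26) and FABP5 (1.5 ± 0.29) rose. In the lipid droplet and triglyceride synthesis list 5 of 15 were higher and 2 lower (5 and 3 adjusted over the list alone; adjusted p = 0.0718). Its median was −0.01 while its mean was 0.35 and its test pointed up. The phosphatidate phosphatase LPIN2 of that list rose by 1.00 ± 0.07. In the fatty acid synthesis list 4 of 14 were higher and 0 lower, both ways of adjusting (adjusted p = 0.172).

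Macrophage and inflammatory transcripts were also higher in oleate cultures. In the macrophage and myeloid list 15 of 21 genes were higher than in control and 0 lower, with the same counts adjusted over the list alone (median 0.74, adjusted p = 0.000164). For macrophage genes, adjusted p = 0.597 with an estimated correlation. They included the invariant chain CD74 (0.74 ± 0.12), the protease CTSS (0.64 ± 0.14), the complement subunit C1QC (1.30 ± 0.30) and lysozyme, LYZ (1.58 ± 0.42). Before oleate was added, at 0 h, CD74 and CTSS were higher still. CD74 had a mean of 8.23 at 0 h, 7.63 in oleate and 6.89 in control, and CTSS 9.59, 9.22 and 8.58. In the inflammatory and NF-kB list 12 of 24 rose and 0 fell, the same adjusted over the list alone (median 0.29, adjusted p = 0.000164). For inflammatory genes, adjusted p = 0.597 with an estimated correlation. Without 1 of the 12 culture series the macrophage list stayed called, with medians from 0.54 (lean control replicate 3, where 6 genes were called) to 0.93. The inflammatory list stayed called as well, with medians from 0.14 (fat oleate replicate 3) to 0.41. Members were the acute phase protein SAA (1.47 ± 0.24), the lipocalin EXFABP (1.24 ± 0.25), NFKB1 (0.31 ± 0.06) and the chemokine CCL4 (0.24 ± 0.03). The calls of C1QC and LYZ were lost when the mean of the macrophage markers entered the fit. Both genes are part of that mean, so their loss cannot tell more macrophages from a change within cells.

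In the glycolysis and hypoxia list 11 of 29 genes rose in oleate and 3 fell, the same adjusted over the list alone (median 0.08, adjusted p = 0.0132). For glycolysis genes, adjusted p = 0.597 with an estimated correlation. The members with the smallest p were the angiogenic factor VEGFA (1.17 ± 0.11), the glucose transporter SLC2A14 (0.32 ± 0.05), PKLR (0.19 ± 0.03) and the vasodilator peptide ADM (0.45 ± 0.10). Stromal lists were not called, but their called members were mostly lower. In the preadipocyte and stromal list 9 of 18 fell and 2 rose, both ways of adjusting (adjusted p = 0.12), with EBF1 at −0.41 ± 0.07 and lumican, LUM, at −0.54 ± 0.09. In the extracellular matrix list 20 of 42 fell and 7 rose (21 and 8 adjusted over the list alone; adjusted p = 0.0718), with COL6A2 at −0.99 ± 0.12 and THBS1 at 0.68 ± 0.06. In the contractile and smooth muscle list 6 of 11 fell and 1 rose, both ways of adjusting (adjusted p = 0.0768), with ACTA2 at −0.62 ± 0.13 and TPM2 at −0.25 ± 0.06.

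The other lists were not called in the oleate effect. Over all genes, 12 of 40 oxidative phosphorylation genes were lower and 1 higher (adjusted p = 0.0718), as were 8 and 4 of 25 unfolded protein and integrated stress genes (0.179). Higher and lower counts were 4 and 1 of 52 for cell cycle (0.723), 7 and 6 of 29 for oxidative stress response (0.356) and 14 and 9 of 60 for cytosolic ribosomal proteins (0.179). They were 5 and 1 of 19 for immediate early and dissociation (0.123) and 0 and 2 of 26 for interferon response (0.145). For markers of other cells they were 3 and 0 of 17 endothelial (0.519), 2 and 0 of 17 lymphocyte (0.506), 0 and 1 of 9 erythroid (0.789) and 3 and 1 of 10 mesothelial and epithelial genes (0.172). Skeletal muscle had 0 and 1 of 6 (0.328) and bone and cartilage 3 and 1 of 11 (0.723). Median and mean differed in sign for the endothelial (−0.05, 0.10), cell cycle (−0.01, 0.01) and bone and cartilage (−0.09, 0.04) lists, whose tests pointed up. Counts adjusted over the list alone were the same, except for 3 and 1 in cell cycle, 0 and 1 in interferon response and 8 and 6 in oxidative stress response.

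In the oleate effect limma called 7726 of 22060 probe sets, 3846 higher and 3880 lower, of which 386 were at least 2-fold higher and 66 at least 2-fold lower. No oleate group shares a style of array names with its control, so no value within a style can be had. Contrasts that set the styles apart without oleate also differ in line, confluence or time. The contrast used was the line difference in the confluence effect, in which the mean differences of line and of confluence cancel but a difference between lines in confluence does not. It called 598 probe sets, 449 of them higher on the dotted side, and over tested probe sets, which are not independent, it correlated with the oleate effect (Pearson r = 0.336, Spearman correlation 0.238). Of the 386 probe sets at least 2-fold higher in oleate, 120 were also called higher in that shift. With the shift subtracted, 155 probe sets were called in the oleate effect, 401 in the lean and 19 in the fat line. Of the genes named above, ACSL1 (1.73 ± 0.31, adjusted p = 0.00273) and ANGPTL4 (2.33 ± 0.59, adjusted p = 0.0428) alone then kept a call in the same direction. NUDCD1 was called in the other direction (−2.02 ± 0.50, adjusted p = 0.0408). PLIN2 was 1.5 ± 0.43 (adjusted p = 0.0849), LUM 0.28 and SREBF2 −0.22. The fatty acid oxidation and PPAR target list was still called, with 2 of 21 higher (3 adjusted over the list alone; median 0.26, adjusted p = 0.00617). For the shifted oxidation list, adjusted p = 0.055 with an estimated correlation. The macrophage and myeloid (median 0.55, adjusted p = 0.464) and inflammatory and NF-kB (median 0.37, adjusted p = 0.464) lists were then not called.

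**Figure D1:**
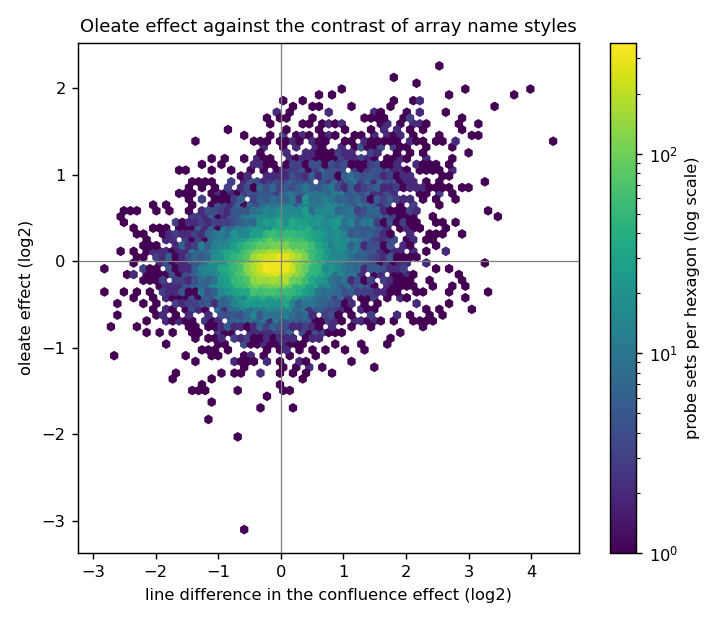
Oleate effect of each tested probe set (log2, oleate minus control) against the line difference in the confluence effect (log2), as hexagons coloured by the number of probe sets on a log scale. The Pearson correlation over probe sets is 0.336.

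A comparison inside the dotted style set oleate at 12 h against 0 h, which differ in time as well as oleate (n = 6 each). It called 121 probe sets, 92 higher and 29 lower. PLIN2 was higher by 1.5 ± 0.21 (adjusted p = 1.52e-05), HADHB by 0.44 ± 0.08 (adjusted p = 0.00292) and ACSL1 by 0.60 ± 0.15 (adjusted p = 0.0476). ANGPTL4, at 1.08, missed the threshold (adjusted p = 0.0662). The other 7 of the 8 largest rises in oleate lay below 0 here and were not called, MARF1 at −0.11, NUDCD1 at −0.22, CPNE3 at −0.49, CEP350 at −0.14, CSF3 at −0.27, S100A12 at −0.67 and IL4I1 at −1.21. The 8 largest falls were not called either, LRRC17 at −1.21, TNFRSF11B at −0.77, PTN at −0.60, C1QTNF3 at −0.41, CDH8 at −0.13, GAS2 at 0, SPTBN5 at 0.02 and BGN at 0.25. Adjusted p of these 15 genes ran from 0.336 to 1. Of the lists called in it, 3 held with an estimated correlation. Cholesterol synthesis had 3 of 20 higher (18 adjusted over the list alone; median 0.61, adjusted p = 3.66e-19, then 0.00675). Fatty acid synthesis had 5 of 14 higher (8 adjusted over the list alone; median 0.39, adjusted p = 3.28e-14, then 0.000143). Fatty acid oxidation and PPAR targets had 2 of 21 higher (8 adjusted over the list alone; median 0.27, adjusted p = 3.61e-07, then 0.000143). Glycolysis and hypoxia had 1 of 29 higher (4 adjusted over the list alone; median 0.14, adjusted p = 2.88e-06, but adjusted p = 0.0698 with an estimated correlation). Inflammatory and NF-kB genes lay the other way from the oleate effect, with a median of −0.13 (0 of 24 called by limma, both ways of adjusting, 1 with an unadjusted p under 0.05; adjusted p = 0.0302, but adjusted p = 0.582 with an estimated correlation). The macrophage and myeloid list was not called, with a median of −0.36 (0 of 21 called by limma, both ways of adjusting, 0 with an unadjusted p under 0.05; adjusted p = 0.072).

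Spike-in RNA, which no cell makes, differed between the oleate and control arrays beside all of these groups. The 36 bacterial poly-A spike-in probe sets were all called lower in oleate (median −0.60), and of 27 hybridization spike-ins 9 were lower and 1 higher. The gap between 3′ and 5′ probe sets, a measure of RNA integrity, differed by 0.007 ± 0.025 for actin and −0.02 ± 0.012 for GAPDH.

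The effect was tested in each line and hour (n = 3 against 3 at each hour). Over the 4 hours 4477 probe sets were called in the lean line (2431 higher, 2046 lower) and 5616 in the fat line (2929 higher, 2687 lower). With culture series as a random block they were 2650 and 3367, and at most 5436 for both lines together. Cholesterol synthesis genes were higher at 12 h, with 5 of 20 called in the lean line (16 adjusted over the list alone; median 0.71, adjusted p = 4.2e-14, and adjusted p = 0.0415 with an estimated correlation). In the fat line 9 of 20 were called (12 adjusted over the list alone; median 0.74, adjusted p = 1.78e-10, but adjusted p = 0.137 with an estimated correlation). At 120 h cholesterol genes were lower, with 3 called in the lean line (6 adjusted over the list alone; median −0.46, adjusted p = 0.000809, but adjusted p = 0.528 with an estimated correlation). In the fat line 1 was called, both ways of adjusting (median −0.31, adjusted p = 0.0133, but adjusted p = 0.618 with an estimated correlation). The macrophage and myeloid list had medians of 1.48, 1.31, 0.76 and 0.66 in the lean line and 0.53, 0.41, 0.37 and 0.74 in the fat line at 12, 24, 72 and 120 h. Its line difference over the 4 hours was not called (median −0.46, adjusted p = 0.0996).

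Calls in the lean line were 745 at 12 h (548 higher), 485 at 24 h (401 higher), 441 at 72 h (388 higher) and 1094 at 120 h (812 higher). In the fat line they were 1409 (875 higher), 716 (558 higher), 1031 (732 higher) and 724 (576 higher). Fitted on only the 6 arrays of a comparison, the count was 2, 274 and 143 in the lean line at 24, 72 and 120 h, and 440, 300 and 43 in the fat line at 12, 72 and 120 h. With array weights it was 1661, 1165, 1067 and 4156 over the lean hours and 3499, 1539, 1552 and 1209 over the fat hours. Single arrays also moved these counts by more than 1.5 times. The lean 12 h count was 326 without control replicate 3 and 408, 410 and 375 without oleate replicates 1, 2 and 3. The lean 24 h count was 274 and 306 without control replicates 2 and 3, and 283 and 255 without oleate replicates 1 and 3. At 72 h in the lean line it was 290 without control replicate 2 and 289 without oleate replicate 3. At 120 h in the lean line it was 700 without control replicate 1 and 652 without oleate replicate 3. The fat 12 h count was 811 and 900 without control replicates 1 and 2, and 563, 557 and 2208 without oleate replicates 1, 2 and 3. The fat 24 h count was 474 and 458 without control replicates 1 and 2, and 436 and 405 without oleate replicates 1 and 2. At 72 h in the fat line it was 529 without control replicate 2 and 560 without oleate replicate 1. At 120 h in the fat line it was 482 without control replicate 2 and 447 without oleate replicate 1.

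**Figure D2:**
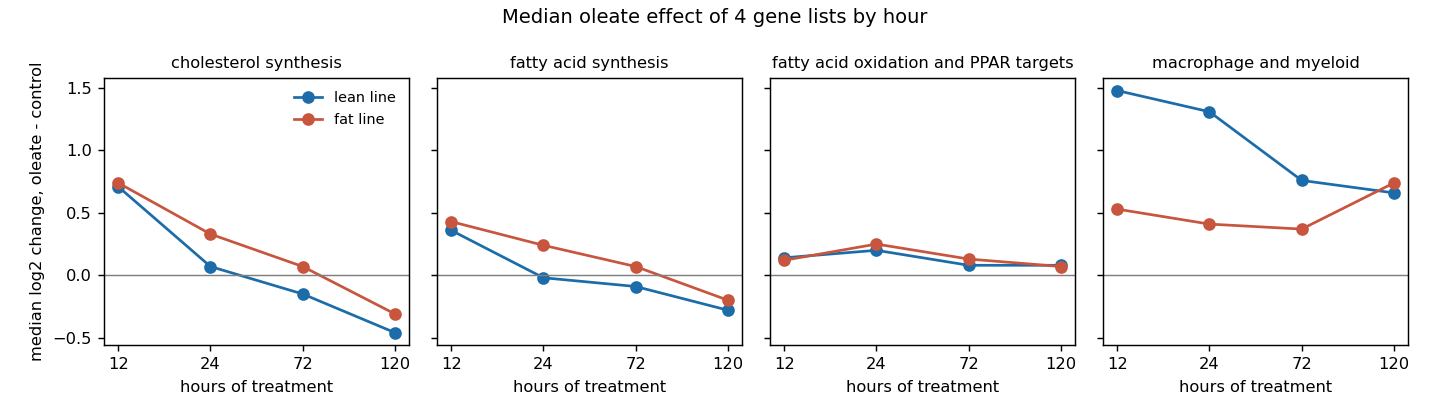
Median log2 difference between oleate and control of 4 gene lists at each hour in each line. Cholesterol synthesis goes from 0.71 (lean) and 0.74 (fat) at 12 h to −0.46 and −0.31 at 120 h.

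The oleate effect on sterol and fatty acid synthesis genes was lower at 120 h than at 12 h. MVD, a decarboxylase of the mevalonate pathway, changed by −2.64 ± 0.38 (adjusted p = 7.48e-05; mean over lines, n = 3 in each of the 8 groups compared). Its oleate effect went from 1.46 to −0.75 in the lean line and from 3.2 to 0.13 in the fat line. Most of this was a rise of MVD in control culture (1.79 ± 0.27, adjusted p = 1.95e-05), beside a fall in oleate culture (−0.85 ± 0.27, adjusted p = 0.0277). INSIG1 changed by −1.48 ± 0.23, from 0.71 to −0.81 in the lean and from 0.91 to −0.53 in the fat line. In the cholesterol synthesis list 11 of 20 genes fell and 0 rose (16 and 0 adjusted over the list alone; median −1.10, adjusted p = 7.41e-40). NSDHL (−1.85 ± 0.30), SC5D (−1.51 ± 0.25) and ACAT2 (−0.84 ± 0.12) were among them. In the fatty acid synthesis list 4 of 14 fell and 0 rose (7 and 0 adjusted over the list alone; median −0.49, adjusted p = 2.09e-12). They were the elongase ELOVL6 (−1.90 ± 0.34), the desaturase FADS2 (−1.39 ± 0.22), ACLY, which makes cytosolic acetyl-CoA (−1.28 ± 0.25), and FASN (−0.63 ± 0.15). Over the cholesterol list the median change was 0.19 in control and −0.91 in oleate culture, and over the fatty acid list 0.16 and −0.47. Of the genes named here, MVD and FADS2 (0.59 ± 0.15) rose in control culture. Both lists held with an estimated correlation (adjusted p = 0.000119 and 0.000429). The oleate effect on the exporter ABCC4 changed by 0.84 ± 0.16, as ABCC4 fell in control (−0.68 ± 0.11) and was not called in oleate culture (0.17 ± 0.11). FASN lost its call in 16 of 24 fits that left out 1 array (adjusted p up to 0.14).

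In 4 other lists the change of the oleate effect with time was called by camera but lost with an estimated correlation. Adipocyte identity had a median of −0.44 (0 of 16 called by limma, 4 with an unadjusted p under 0.05, 4 lower adjusted over the list alone; adjusted p = 0.038). For adipocyte genes, adjusted p = 0.461 with an estimated correlation. Macrophage and myeloid had a median of −0.47 (0 of 21 called by limma, 1 with an unadjusted p under 0.05, 1 lower adjusted over the list alone; adjusted p = 0.038). For macrophage genes, adjusted p = 0.673 with an estimated correlation. Unfolded protein and integrated stress had a median of 0.17 (0 of 25 called by limma, 2 with an unadjusted p under 0.05, 2 higher adjusted over the list alone; adjusted p = 0.00271). For stress genes, adjusted p = 0.673 with an estimated correlation. Glycolysis and hypoxia had a median of −0.08 (0 of 29 called by limma, both ways of adjusting, 5 with an unadjusted p under 0.05; adjusted p = 0.038). For glycolysis genes, adjusted p = 0.673 with an estimated correlation.

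The change of FAM180A (−2.91) was a rise in control culture (3.41 ± 0.49), with 0.51 ± 0.49 in oleate. In all, 67 probe sets were called in the change with time (15 higher, 52 lower), and 1761 had an unadjusted p under 0.05. Of 100 splits of the arrays 10, the real one included, called at least 67, and 4 did with the main effect of time taken out beforehand. The count was 647 with array weights, 140 with culture series as a random block and 44 with only the arrays of the comparison in the fit, where FASN, FAM180A, PKDCCB, RBMS1 and SERAC1 lost their call. Of 66 spike-in probe sets 8 were higher (median 0.20). Without 1 array of the fat control cultures the count was 40 (12 h replicate 1), 42 (12 h replicate 2) and 40 (120 h replicate 3). It was 43 without lean control 120 h replicate 3 and 38 without lean oleate 12 h replicate 3. Without fat oleate 12 h replicates 1, 2 and 3 it was 35, 40 and 140. Calls of SERAC1 (1.01), RBMS1 (0.44), FAM180A (−2.91) and PKDCCB (−1.73) were lost in 18, 14, 16 and 5 of 24 such fits, with adjusted p up to 0.126, 0.115, 0.113 and 0.0656.

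**Figure D3:**
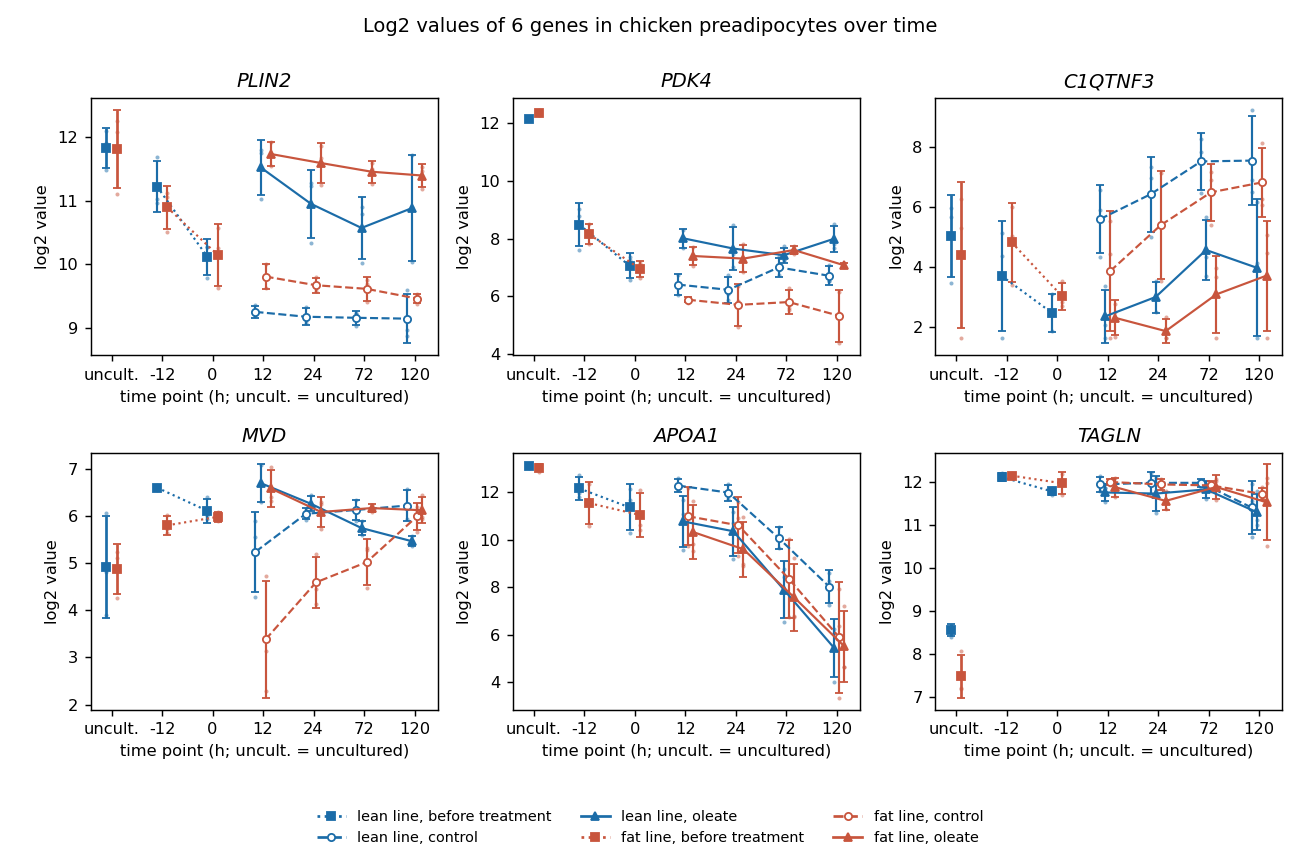
Expression (log2) of PLIN2, PDK4, C1QTNF3, MVD, APOA1 and TAGLN from uncultured cells to 120 h, by line, with and without oleate; lines join group means, bars are SD (n = 3) and dots are single arrays. PLIN2 has a mean of 11.27 in oleate and 9.41 in control cultures.

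Some genes differed between the lines in their response to oleate (n = 12 arrays from 3 series in each line and arm). The fat line had the larger response for the natriuretic peptide gene NPPA (2.30 ± 0.55, adjusted p = 0.0144), the growth factor FGF18 (2.17 ± 0.51, adjusted p = 0.0137) and the mevalonate gene MVD (1.36, adjusted p = 0.00255). The oleate effect was lower in the fat line for ITGBL1 (−2.00 ± 0.51), the serotonin receptor HTR2C (−1.23 ± 0.26) and SLIRP, which binds mitochondrial mRNA (−1.08 ± 0.23). The same held for ARFGEF1, an exchange factor in vesicle transport (−1.07 ± 0.16, adjusted p = 6.76e-05), and the calcium pump ATP2B2 (−0.92 ± 0.22). The interferon response list had a lower response in the fat line (median −0.92, adjusted p = 7.2e-06). For interferon genes, adjusted p = 0.804 with an estimated correlation. Limma called 0 of its 26 members, both ways of adjusting, and 6 had an unadjusted p under 0.05. IFIT5 was at −3.23 ± 1.54 (adjusted p = 0.291) and MX1 at −3.18 ± 1.57 (adjusted p = 0.311). Single culture series carried the list's call. The mean of the list was 8.24, 8.51, 8.84 and 9.25 at 12, 24, 72 and 120 h in fat control replicate 2, against 5.83 and 6.36 at 12 h in replicates 1 and 3. Without that series the median was −0.40 (adjusted p = 0.118), and without fat oleate replicate 1 it was −0.47 (adjusted p = 0.0808). Without fat oleate replicate 3 it was −1.52 with 13 of 26 members called (adjusted p = 1.05e-14), and without fat control replicate 1 it was −1.41 with 0 called (adjusted p = 1.48e-11). Limma called 408 probe sets, 211 higher and 197 lower, 639 without fat oleate 120 h replicate 3, and 2316 with array weights.

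The actin-binding DBN1 (1.77), NTNG1 (1.60) and the potassium channel KCNJ2 (1.41) also met the rule for named genes in the line difference. They lost their call in 11, 25 and 32 of 48 fits that left out 1 array, with adjusted p up to 0.058, 0.0711 and 0.0723. DBN1 and KCNJ2 also lost it without the floor. With culture series as a random block the count was 56. When whole culture series were regrouped between lines, with the main effect of line taken out beforehand, 23 of 100 splits, the real one included, called at least 408 probe sets. Of NPPA, FGF18, DBN1, NTNG1, KCNJ2, ITGBL1, HTR2C, SLIRP, ARFGEF1 and ATP2B2, ARFGEF1 alone kept its call under that block. Of the 36 poly-A spike-in probe sets, 33 were lower in this comparison (median −0.61), and the GAPDH gap differed by −0.054 ± 0.025.

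Between lines in control cultures (n = 12 each, 3 series per line), fat-line cells carried more transcript of GRIA4 (2.03 ± 0.47, adjusted p = 0.00192) and the lipopolysaccharide-binding protein LBP (1.61 ± 0.40). K123 (1.54 ± 0.45), the leukocyte integrin ITGA4 (1.51 ± 0.28), the purine receptor P2RY13 (1.48 ± 0.41) and the chitinase CHIA (1.45 ± 0.42) were higher too. Fat-line cells carried less of the basement membrane protein LAD1 (−2.19 ± 0.34), the keratin KRT13 (−1.91 ± 0.49), the heme-binding protein HPX (−1.89 ± 0.31) and PLCL1 (−1.79 ± 0.40). MAL (−1.76 ± 0.33), synaptophysin, SYP (−1.71 ± 0.44), the VEGF receptor FLT1 (−1.69 ± 0.27) and the exporter ABCC3 (−1.68 ± 0.23) were lower too. Adjusted p of the 8 lower genes ran from 6.86e-07 to 0.00554. Means of PLCL1 (1.89 in the fat and 3.68 in the lean line) and SYP (2.01 and 3.72) lay below the array median of 4.17. So did those of CHIA (3.85 and 2.40), so these differences are between dim values. CHIR-B6 (1.54) and IL1B (1.52) also met the rule for named genes. They lost their call in 8 and 9 of 24 fits that left out 1 array (adjusted p up to 0.0901 and 0.0762).

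Fatty acid synthesis genes were lower in fat-line control cultures, 4 of 14 lower and 0 higher (5 and 0 adjusted over the list alone; median −0.22, adjusted p = 0.00934). For synthesis genes, adjusted p = 0.801 with an estimated correlation. The desaturase FADS2 was at −0.56 ± 0.11 and MCAT at −0.28 ± 0.07. The adipocyte hormone ADIPOQ (−0.98 ± 0.24) and FABP4 (−1.33 ± 0.37) were lower as well. The adipocyte identity list was not called (1 higher and 3 lower of 16; 1 and 4 adjusted over the list alone; adjusted p = 0.79). Nor was the lipid droplet list (2 higher and 3 lower of 15, both ways of adjusting; adjusted p = 0.874), where LPIN2 was higher (0.58 ± 0.09) and ACSL3 lower (−0.35 ± 0.08).

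Macrophage and inflammatory transcripts were higher in fat-line control cultures. In the macrophage and myeloid list 7 of 21 genes were higher and 0 lower (11 and 0 adjusted over the list alone; median 0.83, adjusted p = 9.78e-06). For macrophage genes, adjusted p = 0.801 with an estimated correlation. Lean control replicate 3 had a list mean of 4.72, 5.03, 4.83 and 4.16 at 12, 24, 72 and 120 h, against 5.40 to 6.12 in lean replicates 1 and 2. Without that series the median was 0.42, with 1 gene called (4 with an unadjusted p under 0.05; list adjusted p = 0.0088). Without fat control replicate 1 it was 0.48, also with 1 gene called (list adjusted p = 0.00674). Leaving out 1 of the other 4 series gave medians from 0.77 to 1.18. CTSS was at 0.73 ± 0.20 and CD74 at 0.54 ± 0.17. In the inflammatory and NF-kB list 5 of 24 were higher and 0 lower (6 and 0 adjusted over the list alone; median 0.39, adjusted p = 0.000111). For inflammatory genes, adjusted p = 0.801 with an estimated correlation. Without lean control replicate 3 the inflammatory list had a median of 0.35 with 2 genes called (list adjusted p = 0.00852). The chemokine IL8L2 was at 1.18 ± 0.22 and NFKB1 at 0.35 ± 0.09. Cell cycle genes were lower, 7 of 52 lower and 1 higher, both ways of adjusting (median −0.21, adjusted p = 0.00733). For cycle genes, adjusted p = 0.952 with an estimated correlation. The mitotic genes KIF11 and TTK were at −0.57 ± 0.18 and −0.55 ± 0.17.

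Limma called 3541 probe sets between the lines in control culture, 1710 higher and 1831 lower in the fat line, and 1487 with culture series as a random block. Under that block CD74, KIF11, TTK, CHIR-B6 and IL1B lost their call, and KIF11 also lost it with 0 h as a further time. CD74 lost its call without lean control 120 h replicate 1 (adjusted p = 0.0583) and TTK without fat control 120 h replicate 2 (adjusted p = 0.0515). The calls of CTSS, CD74, KIF11, TTK, P2RY13, CHIA, CHIR-B6 and IL1B were lost with the macrophage marker mean in the fit. CTSS and CD74 are part of that mean, so their loss decides nothing about them. CHIA and CHIR-B6 also lost theirs with only the arrays of the comparison in the fit, and CHIR-B6 and IL1B without the filter and with array weights. All arrays of this comparison have low-bar names. Limma called 0 of 66 spike-in probe sets, with 12 at an unadjusted p under 0.05.

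In uncultured cells the lines could be compared before any passage (n = 3 each, all with dotted names). The fat line was higher for FAM184A (2.84 ± 0.47, adjusted p = 0.000223), OSCP1 (1.71 ± 0.36, adjusted p = 0.00345) and the zinc finger gene ZNF711 (1.64 ± 0.16, adjusted p = 4.03e-09). It was lower for LUZP2 (−3.21 ± 0.55, adjusted p = 0.000273), the ganglioside activator GM2A (−2.92 ± 0.59, adjusted p = 0.00205) and the co-chaperone STIP1 (−2.17 ± 0.31, adjusted p = 1.54e-05). Contractile and smooth muscle genes were lower in the fat line, 4 of 11 lower and 0 higher, both ways of adjusting (median −0.51, adjusted p = 1.24e-06). For contractile genes, adjusted p = 0.0857 with an estimated correlation. The 4 were TPM1 (−0.41 ± 0.07, adjusted p = 0.00025), TAGLN (−1.07 ± 0.26), CALD1 (−0.60 ± 0.16) and ACTG2 (−1.57 ± 0.46), all parts of the actin filament system. Of 42 extracellular matrix genes 1 was called lower, the collagen cross-linker LOXL2 at −1.19 ± 0.29 (2 adjusted over the list alone; list median −0.23, adjusted p = 0.000109). For matrix genes, adjusted p = 0.821 with an estimated correlation.

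Single arrays decided several calls between the uncultured groups. LOXL2 lost its call without lean replicate 2 and without fat replicate 3 (adjusted p up to 0.0906). TAGLN lost it without lean replicate 2 and without fat replicates 2 and 3 (up to 0.0698). CALD1 and ACTG2 lost it in 4 and 5 of 6 such fits (up to 0.181 and 0.2). KCNU1 (1.82), CEP128 (1.80), SLC25A30 (−2.17) and INSYN1 (−1.92), which the rule also names, lost it in 4, 1, 5 and 3 of 6 (up to 0.231, 0.0629, 0.148 and 0.166). LUZP2, INSYN1 and SLC25A30 also lost their call without the floor, OSCP1, KCNU1, INSYN1 and SLC25A30 with array weights, ACTG2 and SLC25A30 without the filter, and ACTG2 with an offset in place of the floor. Limma called 629 probe sets, 287 higher and 342 lower, 417 without lean replicate 2, and 272 with array weights. With the 6 arrays fitted alone it called 8, and none of the genes named for this comparison. Of the 36 poly-A spike-in probe sets 30 were higher in the fat line (median 0.94), and the actin gap between 3′ and 5′ probe sets was wider by 0.188 ± 0.071.

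Most probe sets differed after passage and growth to confluence (0 h minus uncultured, n = 6 each, all with dotted names). Markers of blood, immune and vessel cells, RNA integrity and spike-ins differed too (below), so loss of cells, handling and change within cells were not told apart. The largest rises were MYH15 (7.32 ± 0.42), PKP2 (5.81 ± 0.18), CAPN9 (5.71 ± 0.20) and MKX (5.64 ± 0.18). ACTA1 (5.49 ± 0.38), MYOM3 (5.48 ± 0.31), CXCL14 (5.33 ± 0.56) and PTPRQ (5.32 ± 0.23) followed. The largest falls were TNX (−10.03 ± 0.45), AvBD7 (−8.61 ± 0.48), GIF (−8.46 ± 0.54) and LYG2 (−8.25 ± 0.39). OGN (−8.20 ± 0.30), HBA1 (−8.11 ± 0.38), CD83 (−8.01 ± 0.33) and CD34 (−7.83 ± 0.43) followed. Adjusted p was at most 1.33e-11 for these 16 genes. At 0 h some values lay at the floor of 1.613 for TNX (3 of 6), AvBD7 (2), GIF (1), LYG2 (3), OGN (3) and HBA1 (4), so the size and order of these falls depend on it. Without the floor they were −10.49, −8.83, −8.49, −8.81, −8.90 and −8.82. The rises depend on it too, with uncultured values at the floor for MYH15 (4 of 6), PTPRQ (3), CAPN9 (1) and MYOM3 (1), which were at 7.53, 5.82, 5.86 and 5.82 without it. Limma called 15205 probe sets, 9001 higher and 6204 lower. The median over all tested probe sets was 0.185, and 0.076 with arrays centred on bright probe sets, a shift of 0.109 that changed the sign of 0 of the 24 list medians.

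Markers of blood, immune and vessel cells fell in culture. Of 17 lymphocyte genes 15 fell and 0 rose (median −2.77, adjusted p = 1.67e-06, and adjusted p = 8.25e-05 with an estimated correlation). Among them were the T cell receptor chain CD3E (−7.43 ± 0.49) and JCHAIN of secreted antibodies (−7.37 ± 0.41). CD3E, with 4 of 6 values at 0 h at the floor, was at −8.14 without it. Macrophage and myeloid genes fell at 18 of 21 with 0 higher (median −2.30, adjusted p = 2.3e-05), CD74 by −5 ± 0.24. For macrophage genes, adjusted p = 0.238 with an estimated correlation. Endothelial genes fell at 15 of 17 with 1 higher (median −1.83, adjusted p = 0.00207), with VWF at −2.61 ± 0.23 and the exception ERG at 3.46 ± 0.15. For endothelial genes, adjusted p = 0.0977 with an estimated correlation. Erythroid genes fell at 6 of 9 with 1 higher (median −1.92, adjusted p = 0.02). For erythroid genes, adjusted p = 0.103 with an estimated correlation. Counts adjusted over the list alone were the same for these 4 lists.

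Adipocyte and stromal lists fell in culture as well. Adipocyte identity genes fell at 9 of 16 with 0 higher (8 and 0 adjusted over the list alone; median −0.92, adjusted p = 0.00235), including ADIPOQ (−4.32 ± 0.33) and PPARG, the master regulator of fat cells (−2.24 ± 0.18). For adipocyte genes, adjusted p = 0.0977 with an estimated correlation. Preadipocyte and stromal genes fell at 14 of 18 with 2 higher, both ways of adjusting (median −1.36, adjusted p = 8.96e-05, and adjusted p = 0.0258 with an estimated correlation). EBF1 was at −2.82 ± 0.13 and GATA3, with 3 of 6 values at 0 h at the floor, at −4.47 ± 0.34 (−5.10 without the floor). Among response lists, immediate early and dissociation genes fell at 17 of 19 with 1 higher (median −1.60, adjusted p = 6.25e-06), NR4A3 by −5.32 ± 0.36. For immediate early genes, adjusted p = 0.0977 with an estimated correlation. Inflammatory and NF-kB genes fell at 15 of 24 with 3 higher (median −1.75, adjusted p = 0.000603), NFKB1 by −2.90 ± 0.12. For inflammatory genes, adjusted p = 0.238 with an estimated correlation. Interferon response genes fell at 16 of 26 with 0 higher (median −2.27, adjusted p = 0.000973), IRF1 by −5.34 ± 0.75. For interferon genes, adjusted p = 0.43 with an estimated correlation. Counts adjusted over the list alone were the same for the 3 response lists.

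Growth, contractile and metabolic lists rose in culture. Cell cycle genes rose at 50 of 52 with 0 lower (median 1.84, adjusted p = 7.6e-07), the cyclin CCNA2 by 2.18 ± 0.19. For cycle genes, adjusted p = 0.32 with an estimated correlation. Cholesterol synthesis genes rose at 17 of 20 with 2 lower (median 1.35, adjusted p = 0.000973), FDPS by 3.69 ± 0.24. For cholesterol genes, adjusted p = 0.265 with an estimated correlation. Contractile and smooth muscle genes rose at 9 of 11 with 2 lower (median 2.44, adjusted p = 0.000973), ACTA2 by 4.48 ± 0.26 and TAGLN by 3.86 ± 0.18. For contractile genes, adjusted p = 0.16 with an estimated correlation. Glycolysis and hypoxia genes rose at 22 of 29 with 4 lower (median 0.74, adjusted p = 0.00395), PGAM1 by 1.56 ± 0.07. For glycolysis genes, adjusted p = 0.236 with an estimated correlation. Oxidative phosphorylation genes rose at 36 of 40 with 1 lower (median 0.43, adjusted p = 2.3e-05), CYCS by 1.03 ± 0.06. For respiratory genes, adjusted p = 0.157 with an estimated correlation. Cytosolic ribosomal protein genes rose at 52 of 60 with 1 lower (53 and 1 adjusted over the list alone; median 0.23, adjusted p = 2.3e-05), RPL23 by 1.10 ± 0.10. For ribosomal genes, adjusted p = 0.236 with an estimated correlation. Counts adjusted over the list alone were the same for the other 5 lists. Spike-in probe sets were lower at 0 h, 32 of 36 poly-A (median −0.62) and 27 of 27 hybridization (median −0.51). The 3′ to 5′ gap differed by −0.298 ± 0.05 for actin and −0.25 ± 0.025 for GAPDH (95% intervals up to −0.196 and −0.2).

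From 50% to 95% confluence (n = 6 each) the retinal reductase DHRS3 (2.02 ± 0.33, adjusted p = 2.35e-05), the endothelial cadherin CDH5 (2.36 ± 0.65), TMEM184A (2.14 ± 0.47), RIBC1 (2.00 ± 0.51) and PHRF1 (1.87 ± 0.48) rose. The secreted SPON2 (−2.31 ± 0.35, adjusted p = 7.33e-06), the gelatinase MMP9 (−2.18 ± 0.45), the scavenger receptor SCARF1 (−2.17 ± 0.53) and the vasopressin receptor AVPR2 (−2.07 ± 0.52) fell. Cell cycle genes rose at 20 of 52 (27 adjusted over the list alone; median 0.51, adjusted p = 1.05e-08), CENPF by 1.75 ± 0.35 and NCAPG by 1.06 ± 0.24. For cycle genes, adjusted p = 0.556 with an estimated correlation. Oxidative phosphorylation genes rose at 17 of 40 (21 adjusted over the list alone; median 0.15, adjusted p = 1.8e-07), NDUFB9 by 0.42 ± 0.06 and NDUFS6 by 0.32 ± 0.05. For respiratory genes, adjusted p = 0.119 with an estimated correlation.

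Stress, adipocyte and matrix lists fell with confluence. Unfolded protein and integrated stress genes fell at 9 of 25, both ways of adjusting (median −0.21, adjusted p = 3.18e-05), HERPUD1 by −1.30 ± 0.16 and MTHFD2 by −0.93 ± 0.13. For stress genes, adjusted p = 0.311 with an estimated correlation. Immediate early and dissociation genes fell at 10 of 19 (12 adjusted over the list alone; median −0.41, adjusted p = 1.07e-06), HSPA2 by −0.45 ± 0.09. For immediate early genes, adjusted p = 0.119 with an estimated correlation. Adipocyte identity genes fell at 4 of 16 (6 adjusted over the list alone; median −0.56, adjusted p = 0.00237), PPARG by −0.82 ± 0.18. For adipocyte genes, adjusted p = 0.119 with an estimated correlation. Extracellular matrix genes fell at 8 of 42, both ways of adjusting (median −0.17, adjusted p = 0.00237), TNC by −1.20 ± 0.26. For matrix genes, adjusted p = 0.556 with an estimated correlation. None of the 6 lists called with confluence had a called member in the other direction.

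Limma called 3355 probe sets in the confluence effect, 1844 higher and 1511 lower. The lean arrays of both times have dotted names and gave 420 calls. The fat arrays differ in style between −12 h and 0 h and gave 3097, and the line difference itself gave 598. DHRS3, SPON2, MMP9, HERPUD1, MTHFD2 and NDUFS6 were called in each line by itself. In the lean line alone CDH5, RIBC1, PHRF1, SCARF1, AVPR2, CENPF, NDUFB9, HSPA2 and PPARG lost their call. In the fat line alone CDH5, TMEM184A, RIBC1, AVPR2, NCAPG and TNC lost theirs. AVPR2 also lost its call with no floor and with only the arrays of the comparison in the fit. GREM1 (−2.14), a BMP antagonist, lost its call without lean −12 h replicate 3, fat −12 h replicate 2, lean 0 h replicates 1 and 2 or fat 0 h replicate 3 (adjusted p up to 0.163). Of 66 spike-in probe sets 5 were lower.

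Over time in control culture, from 12 h to 120 h (n = 6 each, all with low-bar names), interferon response genes rose. PLAC8L1 rose by 4.67 ± 1.06 (adjusted p = 0.00324), the antiviral enzyme RSAD2 by 4.66 ± 1.25 (adjusted p = 0.0126), SAMD9L by 3.67 ± 0.85 (adjusted p = 0.00383) and IFI27L2 by 2.85 ± 0.71 (adjusted p = 0.00769). Apolipoprotein APOA1 fell (−4.68 ± 0.63, adjusted p = 4.95e-06), as did the prostaglandin synthase PTGDS (−4.20 ± 0.50), reelin, RELN (−2.73 ± 0.48), the growth factor MDK (−2.59 ± 0.45) and the natriuretic peptide receptor NPR3 (−2.54 ± 0.34). Values at the floor, 4 of 6 for PTGDS at 120 h and 2 of 6 for SAMD9L at 12 h, limit these sizes, which were −4.82 and 4.96 without it. In the interferon response list 22 of 26 genes rose and 0 fell (24 and 0 adjusted over the list alone; median 1.74, adjusted p = 6.25e-14). For interferon genes, adjusted p = 0.48 with an estimated correlation. Without the arrays of a replicate number at every hour the list had 3 called members (lean control replicate 2), 1 (lean control replicate 3), 13 (fat control replicate 1) and 1 (fat control replicate 3). In each of these cases 25 of 26 were above 0. MX1 (4.93), IFIT5 (4.77) and IFI6 (4.68), which the rule also names, lost their call in 8, 9 and 8 of 12 fits that left out 1 array (adjusted p up to 0.108, 0.133 and 0.105). IFI27L2 lost its call with only the arrays of the comparison in the fit.

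**Figure D4:**
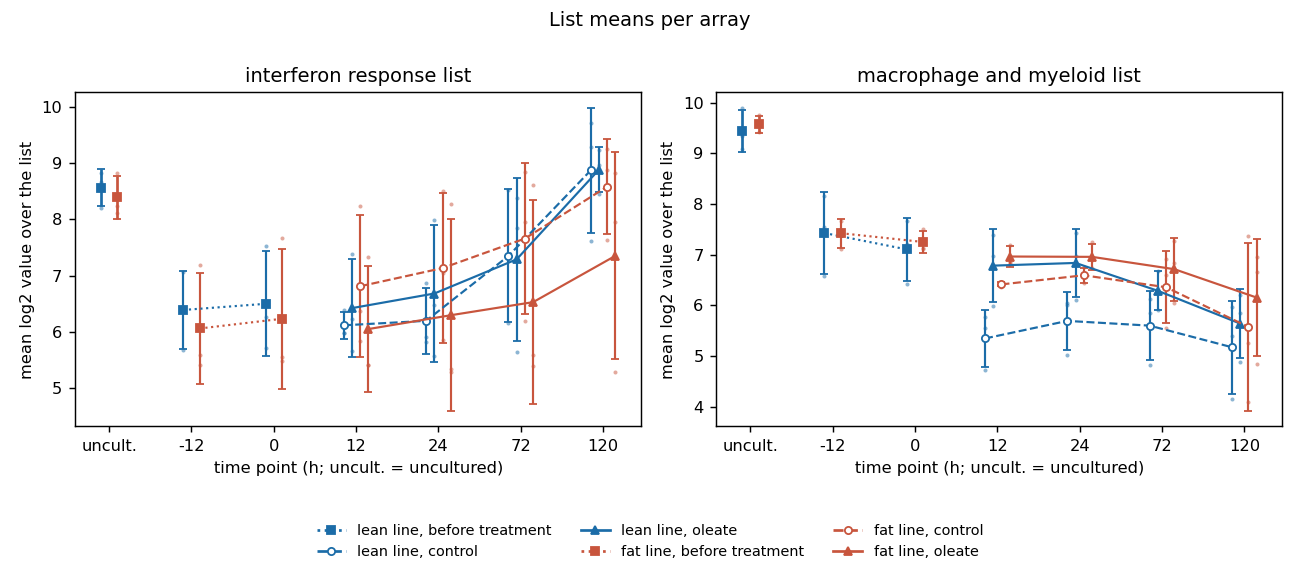
Mean log2 expression of the interferon response and the macrophage and myeloid lists on each of the 66 arrays, by group. In control cultures the interferon list has a median rise of 1.74 between 12 h and 120 h.

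Inflammatory and NF-kB genes rose in control culture at 12 of 24 with 1 lower (16 and 2 adjusted over the list alone; median 0.89, adjusted p = 5.69e-06). For inflammatory genes, adjusted p = 0.48 with an estimated correlation. Members were the adhesion molecule VCAM1 (2.11 ± 0.47), the chemokine IL8L2 (1.40 ± 0.31), the NF-kB inhibitor NFKBIA (1.03 ± 0.26) and PTGS2 (0.70 ± 0.17). Cytosolic ribosomal protein genes fell at 14 of 60 with 0 higher (15 and 0 adjusted over the list alone; median −0.08, adjusted p = 1e-09), RPLP0 by −0.47 ± 0.08 and RPL12 by −0.24 ± 0.04. For ribosomal genes, adjusted p = 0.48 with an estimated correlation. Glycolysis and hypoxia genes rose at 6 of 29 with 1 lower (7 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.00896), the phosphofructokinase PFKP by 0.63 ± 0.12. For glycolysis genes, adjusted p = 0.566 with an estimated correlation. In the cholesterol synthesis list 1 of 20 rose, both ways of adjusting, MVD by 1.79 ± 0.27 (list median 0.19, adjusted p = 0.0236). For cholesterol genes, adjusted p = 0.692 with an estimated correlation. In the cell cycle list limma called 0 of 52, both ways of adjusting, with 8 at an unadjusted p under 0.05 (median −0.23, adjusted p = 0.00896). For cycle genes, adjusted p = 0.772 with an estimated correlation. MVD, IL8L2 and VCAM1 lost their call with 0 h in place of 12 h. Limma called 2064 probe sets, 988 higher and 1076 lower, 1322 without lean control 120 h replicate 3, 3199 with culture series as a random block, 3705 with array weights and 6070 with 0 h in place of 12 h, which also sets the name styles apart. It called 0 of 66 spike-in probe sets, with 5 at an unadjusted p under 0.05.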

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

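Each result here was picked out because 2 groups differed in the same contrast by a test of the difference itself; of the tests weighed, those of RNA integrity, of oleate in the medium and of the macrophage and interferon patterns were chosen after the result was seen.

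The line difference in the oleate effect was called at 408 probe sets, a count that 23 of 100 splits of whole culture series reached, the real one included and the main effect of line taken out. The change of the oleate effect with time was called at 67, which 10 of 100 splits of the arrays reached, or 4 with the main effect of time taken out, and the line difference in the confluence effect, which also sets the styles of array names apart, at 598. Between lines, the response of the interferon response list differed by a median of −0.92 (fat minus lean, camera adjusted p = 7.2e-06, but adjusted p = 0.804 with an estimated correlation). Without the series of fat control replicate 2, whose list mean was 8.24 to 9.25 over the hours, it was −0.40 (adjusted p = 0.118), and without fat oleate replicate 3 it was −1.52 (adjusted p = 1.05e-14). Genes with a larger value in the fat line were NPPA (2.30), FGF18 (2.17), DBN1 (1.77), NTNG1 (1.60), KCNJ2 (1.41), MVD (1.36), ABCC3 (1.31) and RBMS1 (0.44). Genes with a smaller value were ITGBL1 (−2.00), HTR2C (−1.23), SLIRP (−1.08), ARFGEF1 (−1.07), ATP2B2 (−0.92) and VEGFA (−0.82).

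Between 12 h and 120 h, the oleate effect changed by a median of −1.10 in the cholesterol synthesis list, −0.49 in fatty acid synthesis, −0.44 in adipocyte identity, −0.47 in macrophage and myeloid, 0.17 in unfolded protein and integrated stress, and −0.08 in glycolysis and hypoxia; with an estimated correlation the cholesterol and fatty acid synthesis lists alone were called. Sterol genes with a change were MVD (−2.64), NSDHL (−1.85), FDPS (−1.70), SC5D (−1.51), INSIG1 (−1.48), FDFT1 (−1.48), MVK (−1.42), ACAT2 (−0.84) and MSMO1 (−0.70). Fatty acid synthesis genes were ELOVL6 (−1.90), FADS2 (−1.39), ACLY (−1.28) and FASN (−0.63). Other genes were FAM180A (−2.91), PKDCCB (−1.73), SERAC1 (1.01), ABCC4 (0.84) and RBMS1 (0.44).

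The broadest pattern to weigh is the oleate effect itself. A difference in RNA integrity is argued against: the 95% intervals of the difference in the 3′ to 5′ gap of actin and GAPDH reached at most 0.058, within the bound of 0.1 set for it. A batch that follows name style may account for part of the calls. Over tested probe sets the shift between styles correlated with the oleate effect at 0.336, and no oleate array has a control of its style. In that shift 19 of 36 poly-A spike-ins were called lower, 0 higher (median −0.69), and 4 of 27 hybridization spike-ins higher, 0 lower. Handling that differed between oleate and control arrays cannot be told apart from oleate or such a batch. Of 66 spike-in probe sets 46 were called, and every oleate array was set against controls of another style and culture series (−12 h residuals correlated at 0.15 with oleate and 0.014 with control arrays). Oleate in the medium also stays open, as its fatty acid oxidation and PPAR target list had camera p of at most 0.00045 in the 2 contrasts that take the style off (adjusted p = 0.00617, but adjusted p = 0.055 with an estimated correlation) or stay inside it (adjusted p = 3.61e-07, and adjusted p = 0.000143 with an estimated correlation), the second of which differs in time as well as oleate.

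Macrophage and myeloid markers were higher in oleate than in control cultures. More cells of that kind on the oleate arrays cannot be told apart from a change within the cells: 19 of 21 markers were above 0, which is the pattern itself, as were the 5 brightest in uncultured cells, CD74 (0.74), SPI1 (0.98), CTSS (0.64), LAPTM5 (0.86) and C1QB (1.04). None of the 25 listed genes is in another list, and the labels name removal of red cells but no step against macrophages. Between oleate at 12 h and 0 h, all with dotted names, the median of the tested markers was −0.36 (camera adjusted p = 0.072). A shift between name styles cannot be told apart from either, as its median of 0.17 lay below the 0.37 that would have spoken for it, but the 95% interval over markers (−0.02 to 0.28) crossed the 0.19 that would have spoken against it, and the interval of the list mean over arrays ran from −1.41 to 1.72.

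Interferon genes were higher at 120 h than at 12 h in control culture. A virus with sequences among the coding sequence probe sets of the array stays open. Limma called 0 of the 13 tested of 685 higher, and 0 had an unadjusted p under 0.05, which speaks for those 13 alone. The filter passed only probe sets above the array median on all 3 arrays of a group. Sequences of a virus in only some series of a group could have been dropped before the test. As far as replicate numbers mark a series, each control series has arrays at 12 h and at 120 h. An offset between series that is the same at every hour therefore cancels and could not give the rise. The list mean was higher at 120 h than at 12 h in 6 of 6 control series, by 1.01 to 3.33. This is the pattern itself and decides nothing about such an offset. Whether the size of the rise differs between series was not tested. Series did stand apart, with deviations from the group means that correlated at 0.82 between hours (42 pairs of groups, permutation p = 1e-04, the smallest these permutations can give). Time in culture, which the design names, stays open: with culture series as a random block limma called 24 of 26 list members higher.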

How the results depend on the processing

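The further alternatives listed under processing were chosen after seeing the data. The others were planned. All 18 counts stayed within 1.5 times under no filter (52 to 16589), a 70th percentile filter (86 to 10918), no floor (67 to 15094), an offset (69 to 15224), a replicate block (80 to 15309), plain variances (47 to 15198) and bright centring (67 to 14879). Quantile normalization and median centring move nearly nothing in values already alike in distribution, so they test no stability. Signal over background limits dim genes; 20% of values lay at the floor. Replicate numbers did not pair oleate with control arrays of the same line and hour (mean correlation of residuals 0.019 over 24 pairs), nor control arrays with −12 h, 0 h and oleate arrays of any hour (0.012 over 144 pairs). Arrays of the same number went together within control arrays, and within −12 h, 0 h and oleate arrays (0.189 over 126 pairs, all above 0).

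Array weights gave 2316 for the line difference in the oleate effect, 1661, 1165, 1067 and 4156 for the lean hours, 3499, 1539, 1552 and 1209 for the fat hours, 647 for the change with time, 272 for uncultured cells and 3705 for time in control culture; the cause was not tested. One probe set per gene, with fewer tested by construction, gave 3535 for the oleate effect, 2035 in the lean and 2486 in the fat line, 168 for their difference, 238, 141, 148 and 397 for the lean hours, 540, 225, 365 and 233 for the fat hours, 42 for the change with time, 1796 and 289 between lines in control and uncultured cells, 7538 for culture, 1842 for confluence and 1200 for time in control culture. Fitting only the arrays of the comparison, with fewer arrays behind each variance, gave 2, 274 and 143 for the lean line at 24, 72 and 120 h, 440, 300 and 43 for the fat line at 12, 72 and 120 h, 44 for the change with time and 8 for uncultured cells. The lean line alone gave 420 for confluence, and 0 h in place of 12 h gave 6070 for time in control culture and turned ACAT2 there to −0.06; the cause was not tested.

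Less the name style shift, the counts were 155 for the oleate effect, 401 in the lean and 19 in the fat line, in a contrast with a larger error by construction; 43 of 53 named genes lost their call, 2 kept it, and these turned: MARF1 (−0.15), NUDCD1 (−2.02), CPNE3 (−0.75), CEP350 (−0.23), AGPAT2 (0), LUM (0.28), SREBF2 (−0.22) and MYLK (0.05). With culture series as a random block the counts were 2650 in the lean and 3367 in the fat line, 56 for their difference, 140 for the change with time, 1487 between lines in control culture and 3199 for time in control culture; the cause was not tested. With an estimated correlation the lists called were 2 in the change of the oleate effect with time, 2 in the culture effect and 0 in the oleate effect, its line difference, both line comparisons, confluence and time in control culture, because a correlation within lists widens the test.

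Without 1 array the counts ran from 320 to 639 for the line difference in the oleate effect, 35 to 140 for the change with time, 417 to 612 for uncultured cells and 1322 to 2464 for time in control culture. At 12, 24, 72 and 120 h they ran from 326 to 610, 255 to 448, 289 to 428 and 652 to 1587 in the lean line, and from 557 to 2208, 405 to 587, 529 to 803 and 447 to 687 in the fat line. The other 6 counts stayed within 1.5 times. Without 1 culture series the interferon response list in the line difference in the oleate effect had medians from −1.52 to −0.40 and lost its call without fat control replicate 2 (−0.40) or fat oleate replicate 1 (−0.47). In the same way the macrophage list kept its call, with medians from 0.42 to 1.18 for the line difference in control cultures and 0.54 to 0.93 for the oleate effect, as did the inflammatory list (0.30 to 0.52 and 0.14 to 0.41). Of 6684 values of named genes without 1 array, 6377 kept their side of the threshold, 296 lost a call, 11 gained one and 0 turned.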

Other observations

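The change over time within the oleate cultures, 120 h minus 12 h (n = 6 each, both lines), was chosen after the data were seen; so were the splits that keep culture series or take out a main effect, while the other splits of the arrays were planned. Cholesterol synthesis genes fell at 16 of 20 with 0 higher, both ways of adjusting (median −0.91, camera adjusted p = 2.76e-16, and 0.0462 with an estimated correlation), and fatty acid synthesis genes at 8 of 14 (10 lower and 1 higher adjusted over the list alone; median −0.47, adjusted p = 2.17e-05, but adjusted p = 0.0823 with an estimated correlation). Cytosolic ribosomal protein genes fell at 25 of 60 (34 adjusted over the list alone; median −0.09, adjusted p = 1.8e-10, but adjusted p = 0.187 with an estimated correlation), cell cycle genes at 6 of 52 (14 adjusted over the list alone; median −0.36, adjusted p = 1.54e-05, but adjusted p = 0.444 with an estimated correlation), and macrophage and myeloid genes at 5 of 21 (6 adjusted over the list alone; median −0.92, adjusted p = 0.000863, but adjusted p = 0.397 with an estimated correlation).

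Inflammatory and NF-kB genes rose over time in oleate at 15 of 24 with 2 lower (16 and 3 adjusted over the list alone; median 0.91, adjusted p = 1.08e-07, but adjusted p = 0.187 with an estimated correlation). Interferon response genes rose at 8 of 26 with 0 lower (25 and 0 adjusted over the list alone; median 1.31, adjusted p = 1.71e-09, but adjusted p = 0.348 with an estimated correlation), and unfolded protein and integrated stress genes at 8 of 25 with 0 lower (9 and 0 adjusted over the list alone; median 0.10, adjusted p = 0.00754, but adjusted p = 0.39 with an estimated correlation). Limma called 2930 probe sets, 1403 higher and 1527 lower.

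Other splits of the same arrays were fitted 100 times for each larger comparison, the real split included. Since arrays of a culture series go together, splits that keep the series were fitted as well, by moving whole series between lines or arms or by swapping times within a series. Chance was excluded by both kinds for the oleate effect (7726 called, highest other 242, or 5233 with whole series), the confluence effect (3355, highest other 2238, or 1763 with swaps) and time in control culture (2064, highest other 1522, or 576 with swaps), each with 1 split, the real one, as large, of 100 or, for the swaps, of 32. It was excluded for the culture effect (15205 and 12033, 1 of 100 as large), where uncultured arrays have no series. For the oleate effect in the lean line (4477 and 475) and in the fat line (5616 and 894) and the line difference in control cultures (3541 and 150), 1 of 100 splits was as large, but these splits break up the series, and whole series give 10 splits, too few for a share under 0.05, with highest others of 676, 2166 and 1513.

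Splits of a difference between effects carry the main effect of time or line into the regrouped counts, so they decide nothing unless it is taken out. For the line difference in the oleate effect (408 called), 1 of 100 splits of arrays (highest other 49) and 32 of 100 splits of whole series (highest other 5693) were as large with the main effect left in. With it taken out they were 1 (highest other 2) and 23 (highest other 2993), so chance was not excluded once series were kept, and the last count points to a structure of the samples. For the change of the oleate effect with time (67 called), 10 of 100 splits were as large with the main effect left in (highest other 3621). With it taken out 4 of 100 splits of arrays (highest other 274) and 3 of 100 swaps within series (highest other 84) were as large. Both shares were under 0.05, but these 2 tests were chosen after the data were seen. Chance was therefore not firmly excluded.

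With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real and highest other values were 745 and 1, 485 and 2, 441 and 1, and 1094 and 642 in the lean line at 12, 24, 72 and 120 h, 1409 and 68, 716 and 1, 1031 and 17, and 724 and 1233 in the fat line (2 splits as large at 120 h), and 629 and 463 in uncultured cells.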
